A study of Mus musculus with 8 samples.

How the data were processed

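RNA from primary mouse embryonic fibroblasts of 2 lines, with and without tamoxifen, was hybridised to Affymetrix microarrays, 8 arrays in all. Per the labels, the authors normalized the intensity files by RMA in Affymetrix Expression Console, whose version is not given in the sources used here. RMA corrects the background, quantile-normalizes the arrays and summarises the probes of a probe set as a log2 value, which compresses differences between dim probe sets and assumes similar distributions on all arrays. The deposited table holds these log2 values, 1 column per sample; the log2 scale follows from RMA and from values that lie between 2.61 and 14.12. The columns are not centred by gene. The medians over all probe sets were 7.20 and 7.19 (line A without tamoxifen), 7.18 and 7.18 (line A with), 7.18 and 7.20 (line B without) and 7.17 and 7.24 (line B with). No array was normalized again for the main results. No detection calls were used, and dim probe sets near background understate a change.

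The titles of the samples name the line and the treatment, and these set the groups. Some other label fields speak of mammary tumors, while the titles, the source and the design text speak of embryonic fibroblasts, which is how the samples were treated here. The labels number no replicates, so replicate numbers follow the order of the samples and pair nothing.

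The table holds 35556 probe sets. GEO's platform annotation gave 1 gene symbol for 21789 of them and several for 1621, and 12146 are unnamed here. Gene IDs of 21698 matched the RefSeq gene table, which changed 0 symbols. A gene with more than 1 probe set (999 genes) was represented by the probe set with the highest mean over the 8 samples, which left 19938 genes. Genes whose probe sets carry several symbols were not named, so Cdkn1a among others was not analysed here.

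Tests were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The effect over both lines came from a model with line and tamoxifen on all 8 samples, with 5 residual degrees of freedom. The effect in each line, the difference between those effects and the difference between the lines without tamoxifen came from a model of the 4 group means, with 4 residual degrees of freedom. In total 35 gene lists were written down before the data were examined, with 703 genes of which 648 were measured. They were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 35 lists, and again with the correlation estimated and with fry. Counts adjusted over the list alone apply the adjustment to the members of 1 list.

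The genes named were set by a rule: the 12 largest rises and the 12 largest falls among genes that passed with the same sign in both lines, 6 of each for the other comparisons, 5 per direction with the smallest p where none passed, up to 4 members with the smallest p of each list described, and 10 genes fixed in advance, with 5 sex-linked genes between the lines, of which those measured are reported. Symbols of unnamed transcripts, microRNAs, small nucleolar RNAs and olfactory or vomeronasal receptors were left out. Genes named in other places were chosen after their values were seen.

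The fits were tested on simulated data, 10 sets of 8 arrays for 19938 genes, with 200 changed genes in each. They were made from the measured means, spreads and the leading axis of variation within groups. Scores on that axis were drawn at random over the 8 samples, on average weaker within groups than measured and no larger in line B. The shares found may thus be too high, and the calls of other lists too few. For tamoxifen over both lines, changes of 1 and 0.5 (log2) were found for 98.8% and 71.8% of genes that rose, and changes of -1 and -0.5 for 96% and 73.2% of genes that fell. In line A, rises of 1 and 0.5 were found for 85% and 28.6%, and in line B for 86.4% and 33.6%. A list changed by 0.5 was found in 10 of 10 sets. Camera with the preset correlation also called up to 6 of the other 34 lists, with a median of 1, and with an estimated correlation it called 0.

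Alternatives set before the data were examined were a shift of the arrays to a common median, quantile normalization again, leaving out the 30% dimmest genes, eBayes with trend and robust, array weights, the mean of a gene's probe sets, every probe set on its own, leaving out each sample in turn, and for the effect over both lines other ways to treat the line. Leaving out the arrays at one end of the leading axis of variation within groups, and that axis as a covariate, were added after seeing the data.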

Results

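Gene expression was measured in primary mouse embryonic fibroblasts, cells taken into culture from embryos, on Affymetrix microarrays. There were 2 fibroblast lines, line A and line B, and each was sampled without tamoxifen, when the cells expressed the PKM2 isoform of pyruvate kinase, and with tamoxifen, when they expressed the PKM1 isoform. Each of the 4 groups held 2 samples, 8 arrays in all. Pyruvate kinase catalyses the last step of glycolysis, and the comparison asks which transcripts differ when cells that make the PKM2 isoform make PKM1. Values are log2 expression values, and differences are log2 fold changes, tamoxifen minus no tamoxifen unless stated otherwise, with standard errors from limma. Across 19938 genes, samples of one group correlated at 0.9974 (line A with tamoxifen), 0.9956 (line A without), 0.9907 (line B without) and 0.9894 (line B with), so the line B samples were further apart. The labels do not say whether the samples of a group were separate cultures, so the p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision.

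Pkm, the gene that encodes both isoforms, did not pass the test with either of its probe sets. Its brighter probe set averaged 11.05 without and 10.94 with tamoxifen, a log2 fold change of -0.11 (SE 0.15, n = 8 samples, adjusted p = 0.88, 95% interval -0.44 to 0.22). A second Pkm probe set gave -0.41 (SE 0.19, adjusted p = 0.52 over the named probe sets, 95% interval -0.83 to 0.01), and the mean of the probe sets -0.26 (SE 0.16). The exons that these probes match were not analysed here, so neither probe set checks the exchange of isoforms. Pklr, which encodes the pyruvate kinase of liver and red cells, was at 6.98 and 6.96, a change of -0.02 (SE 0.07, adjusted p = 0.96).

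Interferon-induced transcripts rose and cell cycle transcripts fell with tamoxifen in the fit over both lines. The largest rise was that of Ifit1, an interferon-induced antiviral RNA-binding protein, which went from 6.41 to 8.87, 5.48-fold higher (log2 fold change 2.45, SE 0.14, adjusted p = 0.00011). Its relatives Ifit3 and Ifit3b rose 4.15-fold and 4.00-fold, and Mmp13, a collagenase, rose 2.72-fold. Among the largest falls were the gap junction gene Gjb2 (log2 fold change -0.80, SE 0.10), the replication gene Wdhd1 (-0.72, SE 0.07), the proliferation marker Mki67 (-0.70, SE 0.09) and the cyclin gene Ccna2 (-0.67, SE 0.09). In the fit over both lines, 263 of 19938 genes passed an adjusted p of 0.05 in limma, 161 higher and 102 lower. All 23 that changed at least 2-fold were higher.

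Of the 263 genes, 263 had the same sign in both lines, and in 213 the 4 samples with tamoxifen and the 4 without did not overlap. These genes were chosen in the same samples for a change common to both lines, so both counts largely follow from that choice. Over all genes tested, 59.2% had the same sign in both lines. Among all genes tested 5.31% were separated in this way, where chance alone gives 2.86%. The count of 263 rested on single arrays of line A: it fell by more than 1.5 times without any 1 of them. Without any 1 of the line B arrays it stayed within 1.5 times. The change was larger in size in line A for 201 of the 263 genes.

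**Figure D1:**
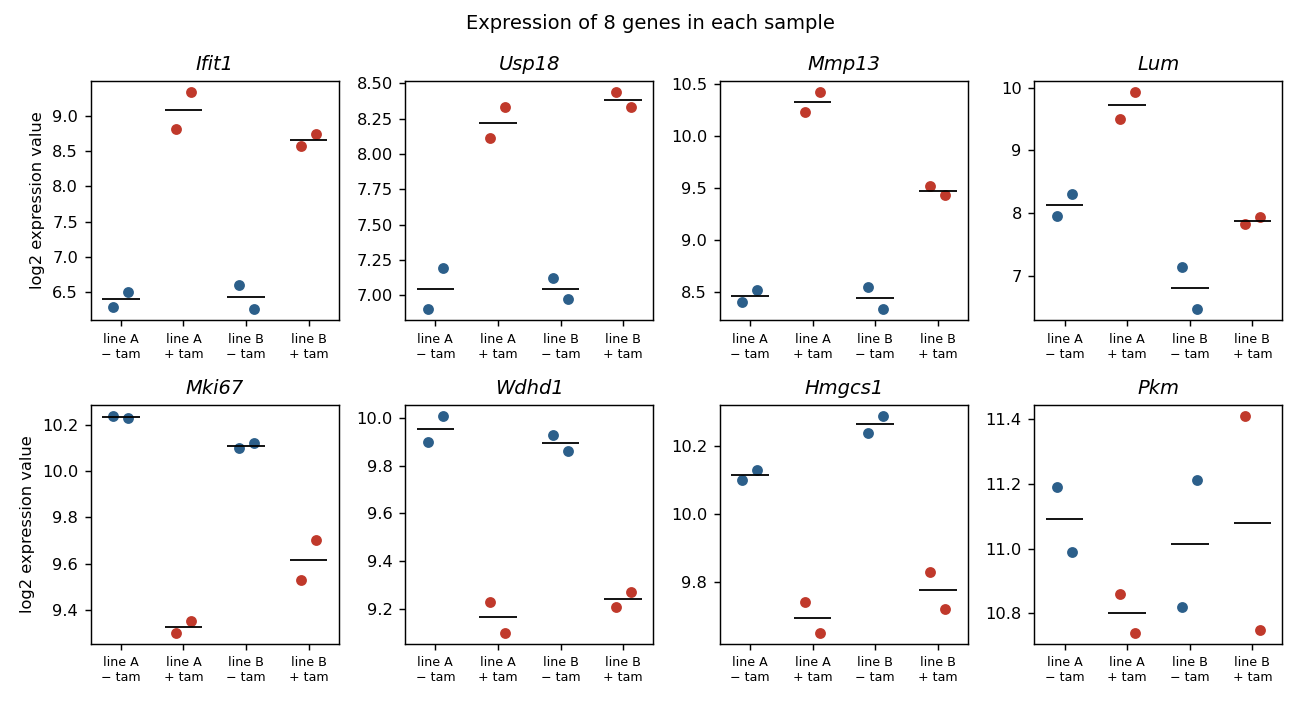
Log2 expression value (vertical axis, not starting at 0) of 8 genes in each sample, with 2 points and their mean (black line) per group; blue is without and red with tamoxifen. The samples with tamoxifen lie above the others for Ifit1, Usp18 and Mmp13 and below them for Mki67, Wdhd1 and Hmgcs1, Lum is higher with tamoxifen within each line, and the Pkm points overlap in line B (10.82 and 11.21 without, 11.41 and 10.75 with tamoxifen) but not in line A (11.19 and 10.99 without, 10.86 and 10.74 with).

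Of the 27 measured genes on the interferon response list, 13 rose, 0 fell and 14 did not pass the test over all genes; adjusted over the list alone, 18 rose. Besides Ifit1, Xaf1 rose by 1.44 (SE 0.12), Usp18, which encodes a protease that limits interferon signalling, by 1.26 (SE 0.09) and Ifih1, a sensor of viral RNA in the cytosol, by 1.12 (SE 0.10). The median change of the list was 0.49, 0.53 in line A and 0.44 in line B. Camera gave an adjusted p of 2.9e-28 for the list, and 0.013 with an estimated correlation. The markers of macrophages and other blood cells, which also carry interferon-induced transcripts, had a median change of 0.03 and 0 of 16 genes passed (camera adjusted p = 0.22); in line B their median was 0.11 (0.042, or 0.42 with an estimated correlation). Close relatives were among the 12 largest rises, the Ifit genes Ifit1, Ifit3 and Ifit3b, Trim30a (1.39, SE 0.17) and Trim30d (1.31, SE 0.08), and Ifi203 (1.83, SE 0.16), whose family has many members; whether their probes match several relatives was not analysed here. The 12 also held Rtp4 (1.47, SE 0.11), Oasl2 (1.30, SE 0.13) and the matrix proteoglycan gene Lum (1.33, SE 0.17).

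Mitosis genes fell together. Of 38 measured, 17 fell, 0 rose and 21 did not pass; adjusted over the list alone, 36 fell. Ect2, required for cytokinesis, fell by 0.61 (SE 0.07), and Kif23, a motor of the central spindle, by 0.57 (SE 0.08). The median change was -0.42 (camera adjusted p = 4.7e-40, and 0.045 with an estimated correlation). Of 40 DNA replication genes, 5 fell, 0 rose and 35 did not pass; adjusted over the list alone, 18 fell. Pole, the catalytic subunit of a replicative polymerase, changed by -0.49 (SE 0.08), Uhrf1 by -0.50 (SE 0.09), and Mcm6 and Mcm4, parts of the replicative helicase, by -0.45 (SE 0.08) and -0.35 (SE 0.07); the list's median was -0.24 (camera adjusted p = 1.5e-17, and 0.045 with an estimated correlation). The remaining large falls included Cdc25c (-0.64, SE 0.09), Ticrr (-0.64, SE 0.10), Pclaf (-0.63, SE 0.09) and Cenpn (-0.61, SE 0.09), all with known roles in the cell cycle. Sema3a (-0.69, SE 0.06), Abi3bp (-0.72, SE 0.08) and Rab39b (-0.65, SE 0.08) fell as well.

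A few nucleotide and one-carbon genes fell. On the list of pyrimidine and deoxynucleotide synthesis, 1 of 18 genes fell, Dut, which hydrolyses dUTP (-0.39, SE 0.08); adjusted over the list alone 2 fell, and the camera adjusted p was 0.0016, or 0.20 with an estimated correlation. Of 12 serine and one-carbon genes, 2 fell, the mitochondrial folate enzymes Mthfd2 (-0.43, SE 0.07) and Aldh1l2 (-0.65, SE 0.12), and 5 did adjusted over the list alone; the camera adjusted p was 7e-06, or 0.22 with an estimated correlation. Of 31 targets of ATF4, the transcription factor of the amino acid response, 2 fell, Mthfd2 and the cystine transporter gene Slc7a11 (-0.47, SE 0.09), and 8 did adjusted over the list alone; the camera adjusted p was 1.5e-09, or 0.25 with an estimated correlation. Mthfd2 is on both of these lists, which share 3 genes. Purine synthesis had a median of -0.07 and 0 of 14 genes passed over all genes, with 1 higher adjusted over the list alone, Prps2 at 0.32 (SE 0.08).

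A few lipid synthesis genes fell. Of 19 cholesterol synthesis genes, 3 fell, Hmgcs1 (-0.45, SE 0.06), Fdps (-0.34, SE 0.06) and Insig1 (-0.38, SE 0.08), and 10 did adjusted over the list alone; Hmgcs1 and Fdps encode enzymes of the pathway and Insig1 a membrane protein that restrains it. The camera adjusted p was 8e-10, or 0.18 with an estimated correlation. Of 11 fatty acid synthesis genes, 1 fell, the elongase gene Elovl6 (-0.59, SE 0.07), the same number as adjusted over the list alone; the camera adjusted p was 1.9e-05, or 0.29 with an estimated correlation.

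Some targets of p53 and some secreted factors known from senescent cells rose. Of 20 p53 targets, 3 rose, Perp (0.52, SE 0.07), Mdm2 (0.35, SE 0.06) and the death receptor gene Fas (0.61, SE 0.12), and 9 did adjusted over the list alone; the camera adjusted p was 2.3e-06, or 0.083 with an estimated correlation. Of 30 senescence-associated secreted factors, 7 rose and 1 fell, with 8 and 1 adjusted over the list alone. Besides Mmp13, the chemokine genes Ccl2 and Ccl7 rose by 0.63 (SE 0.07) and 0.58 (SE 0.07) and the protease gene Mmp3 by 1.21 (SE 0.19). The mean of this list was 0.24 and its median 0.07, since a few members carried the change (camera adjusted p = 6.5e-06, and 0.045 with an estimated correlation). Cdkn2a, a marker of senescence, was at 7.10 in both conditions (log2 fold change 0.00, SE 0.06). That is close to the median over all probe sets, and no detection calls were used, so Cdkn2a may not have been detected. Of 9 CDK inhibitors and pocket proteins, 1 fell, Cdkn2c (-0.43, SE 0.07); adjusted over the list alone 3 rose and 2 fell. Of 10 fibroblast markers, 2 rose, Lum and Dcn (0.88, SE 0.15), and 3 did adjusted over the list alone (camera adjusted p = 0.0088, or 0.20 with an estimated correlation and 0.15 with no term for the line).

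Another 5 lists passed camera with no single gene past the threshold, over all genes or, but for 1 of the splicing factors, adjusted over the list alone. Their medians were 0.15 for 18 lysosome and autophagy genes (adjusted p = 8.6e-05), 0.09 for 35 oxidative phosphorylation genes (0.0059), -0.12 for 17 genes of the unfolded protein response (0.0022), -0.05 for 23 MYC targets (0.027) and -0.24 for 3 PKM splicing factors (0.011). With an estimated correlation their adjusted p-values were 0.43, 0.45, 0.23, 0.29 and 0.18. Single arrays decided some of these calls: the lysosome and autophagy list had a median of 0.03 without line B PKM1 replicate 1 (adjusted p = 0.096) and oxidative phosphorylation 0.04 without line A PKM2 replicate 1 (0.28), and MYC targets did not pass when any of 5 of the 8 arrays was left out. In line B the mean of the lysosome and autophagy list was 9.84 and 10.02 without and 10.25 and 9.79 with tamoxifen, so the samples overlapped. Of the splicing factors, Ptbp1 changed by -0.64 (SE 0.28) and Srsf3 by -0.24 (SE 0.06), and neither passed. In all, 16 of 35 lists passed camera with the preset correlation, 6 higher and 10 lower, and 4 passed with an estimated one. Other splits of the 8 samples gave up to 17 lists with the preset correlation and 0 with an estimated one. Such splits can hold more samples with tamoxifen on one side than on the other. Their counts can thus include part of the tamoxifen effect.

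Glycolysis did not pass. Of its 17 measured genes 0 passed, the median was -0.05 (camera adjusted p = 0.58), and Ldha, the enzyme that turns pyruvate into lactate, was at 12.31 without and 12.01 with tamoxifen (log2 fold change -0.30, SE 0.19, 95% interval -0.73 to 0.13). Medians lay at 0.02 for the pentose phosphate pathway, 0.02 for pyruvate entry and the TCA cycle, 0.01 for HIF1 targets, -0.01 for beta-catenin targets, 0.11 for NRF2 targets and -0.01 for ribosomal proteins. Hif1a (0.13, SE 0.07), Ctnnb1, which encodes beta-catenin (0.03, SE 0.10), Myc (-0.20, SE 0.09) and Esr1 (-0.09, SE 0.11) did not pass. Estrogen receptor targets, listed because tamoxifen binds that receptor, had a median of -0.09, and 1 of 11 rose, the growth factor gene Igf1 (0.51, SE 0.07). For other tissues and cell states the medians were -0.02 for matrix and myofibroblast genes, -0.04 for immediate early genes, 0.02 for Hox genes, -0.03 for adipocyte, 0.01 for skeletal muscle, -0.09 for neural and glial, -0.05 for epithelial and mammary and -0.01 for endothelial markers. In the neural and endothelial lists 1 gene each fell, Map2 (-0.38, SE 0.07) and Erg (-0.44, SE 0.07). Adjusted over the list alone, 1 gene was higher and 1 lower on the estrogen receptor, Hox and neural lists, 1 higher on the TCA cycle list and 1 lower on the endothelial list. The 19 lists that did not pass had camera adjusted p-values from 0.075 to 0.95. The median, the mean and the direction of the test differed in sign for the pentose phosphate, CDK inhibitor, skeletal muscle and beta-catenin lists.

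**Figure D2:**
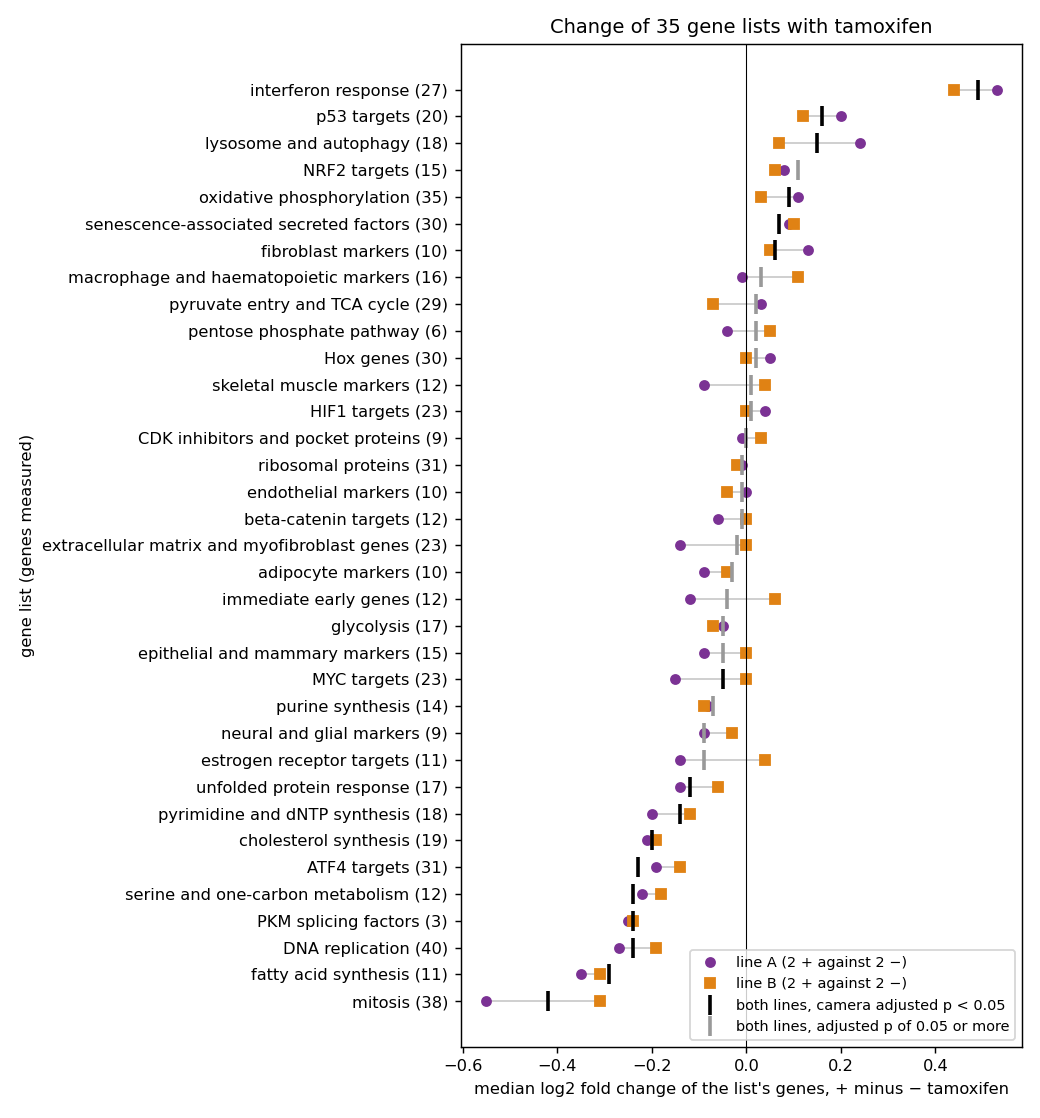
Median log2 fold change, tamoxifen minus no tamoxifen, of the measured genes of each of 35 lists (number of genes in brackets), in line A (circles), line B (squares) and over both lines (bars, black where the camera adjusted p was under 0.05). The mitosis list lies furthest to the left, at -0.42 over both lines, and the interferon response list furthest to the right, at 0.49; the median over both lines is taken over genes, so it need not lie between the others.

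In line A alone, 100 genes passed in limma, 80 higher and 20 lower. The largest rises were those of Ifit1 (2.68, SE 0.18), Ifit3 (2.22, SE 0.34), Ifi203 (1.97, SE 0.24), Ifit3b (1.87, SE 0.26), Mmp13 (1.86, SE 0.11) and Mmp3 (1.71, SE 0.16). The largest falls were those of Mki67 (-0.91, SE 0.09), Gjb2 (-0.90, SE 0.14), Pclaf (-0.84, SE 0.09), Ticrr (-0.84, SE 0.11), Ccna2 (-0.81, SE 0.12) and Wdhd1 (-0.79, SE 0.10). Of the mitosis genes 6 fell (adjusted over the list alone 35 fell and 1 rose), of the DNA replication genes 1 fell (10), and of the interferon response genes 6 rose (17). These 3 lists passed camera with both correlations, and 18 of 35 did with the preset one. In a fit of the 4 line A samples alone the count was 543, and without any 1 of these 4 samples it was between 0 (without line A PKM2 replicate 1) and 6.

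In line B alone, 4 genes passed, all higher: Ifit1 (2.23, SE 0.18), Trim30d (1.40, SE 0.12), Usp18 (1.34, SE 0.13) and Mmp13 (1.03, SE 0.11). These SEs pool the spread over both lines, although the line B samples were further apart. A fit of the 4 line B samples alone called 2 genes, of which 1 is among these 4. Under 19 alternative settings the call was lost in 15 for Mmp13, 10 for Usp18, 6 for Trim30d and 5 for Ifit1. At an unadjusted p under 0.05 there were 962 genes in line B, against 1614 in line A. Over all genes tested, the count in line B is no more than chance alone gives at that threshold. The median of the mitosis list was -0.31 in line B and passed camera (adjusted p = 1.1e-26, or 0.062 with an estimated correlation), and that of the interferon list was 0.44 (1.7e-23, or 0.047 with an estimated correlation). In line B 0 of 38 mitosis and 0 of 40 DNA replication genes passed over all genes, and the replication list's median of -0.19 passed camera (1.9e-10, or 0.06 with an estimated correlation). Adjusted over the list alone, 14 mitosis genes and 0 DNA replication genes fell and 16 interferon response genes rose. With the preset correlation 13 of 35 lists passed, and with an estimated one 1 did. The count was 0 without line B PKM2 replicate 2 and without line B PKM1 replicate 1, 1 without either line A PKM1 sample, and 2 without line B PKM1 replicate 2.

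Of the 100 genes that passed in line A, 97 had the same sign in line B, and 91 of the 100 had the larger change in line A, the line in which they were chosen. Across all genes, which are not independent replicates, the log2 fold changes of the lines correlated with a Pearson r of 0.489 and a Spearman rho of 0.303, and 59.2% had the same sign. Without line B PKM2 replicate 2 the Pearson r was 0.176, the Spearman rho -0.026, and 46.2% had the same sign; without line B PKM1 replicate 2 the Pearson r was 0.304. The test of the difference between the lines called 0 genes in limma, with 565 at an unadjusted p under 0.05. That is fewer than chance alone gives over all genes tested. The smallest p-values belonged to Rdh9, COX2, Klk15, Lypd11 and AI506816, whose change was higher in line B, and to Agtr2, Robo2, Dcn, C1s1 and Mmp13, whose change was higher in line A; none of these passed, the adjusted p being 1 for each. For Agtr2, an angiotensin receptor, the difference was -1.31 (SE 0.23), from 1.45 in line A to 0.14 in line B.

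Among the lists, 6 passed camera for a difference between the lines and 0 did with an estimated correlation or in fry. Mitosis genes changed by a median of -0.55 in line A and -0.31 in line B (adjusted p of the difference 2.9e-07, or 0.50 with an estimated correlation), and DNA replication genes by -0.27 and -0.19 (0.0089, or 0.46 with an estimated correlation). Fibroblast markers, which include Dcn, changed by 0.13 and 0.05 (0.0028, or 0.46 with an estimated correlation).

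**Figure D3:**
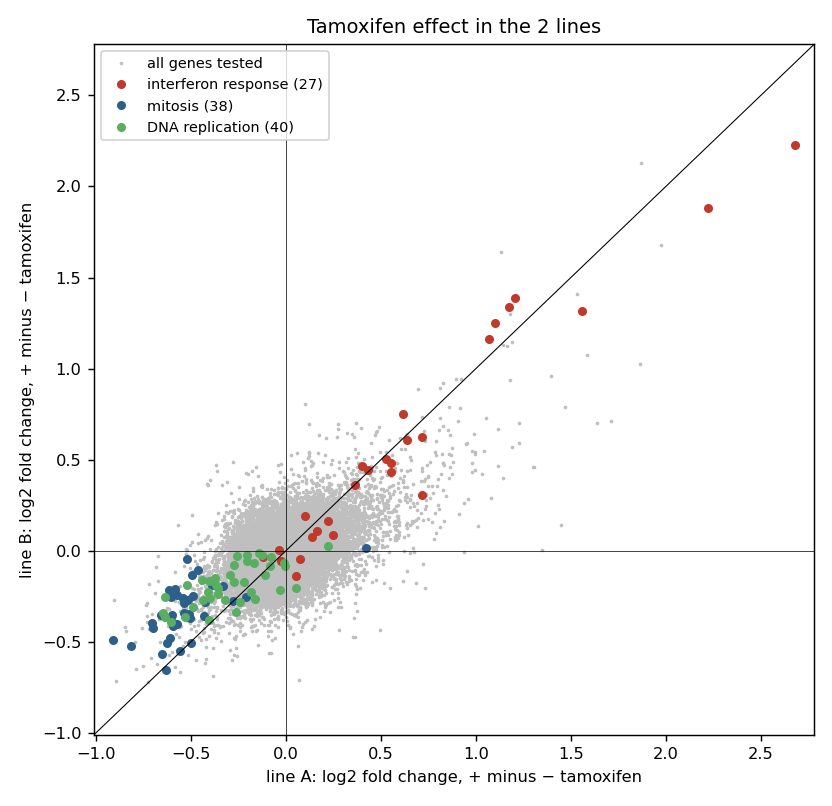
Log2 fold change with tamoxifen in line A (horizontal axis) and line B (vertical axis) of 19938 genes (grey), with the 27 interferon response (red), 38 mitosis (blue) and 40 DNA replication genes (green); the diagonal marks equal change. The red points run along the diagonal up to Ifit1 at 2.68 and 2.23, and most blue points lie left of it, with medians of -0.55 and -0.31.

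Without tamoxifen the lines differed in 65 genes in limma, 37 higher and 28 lower in line B. The difference was 2.14 (SE 0.19, 4.41-fold) for Lyz2, the lysozyme gene of macrophages and granulocytes, 1.73 (SE 0.10) for the scavenger receptor gene Olr1, 1.61 (SE 0.14) for the protease gene Ctss, 1.56 (SE 0.10) for Tfpi2, 1.36 (SE 0.21) for Plac8 and 1.35 (SE 0.17) for the leukocyte receptor gene Lilr4b. Lower in line B were Penk (-1.58, SE 0.12), Cd59a (-1.45, SE 0.15), Abi3bp (-1.44, SE 0.12), Prg4 (-1.19, SE 0.11), Lrrtm3 (-1.13, SE 0.11) and Adgrg2 (-1.12, SE 0.12). Of 16 macrophage and blood cell markers, 1 passed over all genes, Lyz2, and 8 were higher adjusted over the list alone; the median was 0.37 (camera adjusted p = 3.5e-11, or 0.16 with an estimated correlation). Cholesterol synthesis genes had a median of 0.16, 0 of 19 passed, and camera gave an adjusted p of 9.3e-06, or 0.97 with an estimated correlation. Of the fibroblast markers, Fap (1.20, SE 0.13), Dcn (0.87, SE 0.11) and Thy1 (0.64, SE 0.09) were higher in line B and 0 were lower, or 3 and 1 adjusted over the list alone. The list's median was -0.02, with 6 of 10 genes below 0, and Lum, at 8.13 in line A and 6.81 in line B, had the largest difference (-1.32, SE 0.23) but did not pass (adjusted p = 0.069). Xist, which is expressed from the inactive X chromosome, was at a similar level in the lines (-0.16, SE 0.11), and the Y-linked genes Kdm5d, Uty and Eif2s3y differed by 0.03 (SE 0.12), 0.10 (SE 0.13) and 0.08 (SE 0.10); none passed. The count fell to 4 without either line A PKM2 sample, to 15 without either line A PKM1 sample, and to 17 and 24 without line B PKM2 replicate 1 and replicate 2.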

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

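The tests of the chance splits and of leaving out arrays were set down before their results were seen, but the arrays to leave out were picked after seeing the data; the tests on macrophage markers, on the level of mitosis genes without tamoxifen, on the treatment itself and on splits that keep the lines balanced were chosen after the result was seen. For the mitosis gap, the comparison with a standard error was added after its value was seen.

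With the line as a term, 34 splits of the 8 samples into 4 and 4 can be fitted. Of these 1, the real one, called as many as 263 genes, and the highest count in the others was 0. With the preset correlation 2 of the 34 splits, the real one and one with 17, called as many as 16 lists. The split with 17 kept most samples with tamoxifen on the same side, and its medians were 0.28 in size for mitosis and for interferon. Its count can thus hold part of the tamoxifen effect. With an estimated correlation the real split called 4 lists and the others 0, and 1 of 34 splits reached that count. The size of the median change reached 0.42 for mitosis, 0.24 for DNA replication and 0.49 for the interferon list. The other splits reached 0.35, 0.17 and 0.36 at most, so 1 of 34 splits, the real one, reached each median. For the secreted factors the median of 0.07 was reached by 7 of the 34 splits, and the highest other was 0.14, so chance is not excluded for that median. Samples can be exchanged only within a line, so chance is judged by the splits that keep 2 samples of each line on each side. Only 18 of the 34 splits do, too few for a share under 0.05. Chance is therefore not excluded for the counts or the medians. Among the 18 splits the highest other values were 0 genes, 15 lists and 0 lists with an estimated correlation. The highest other medians were 0.33 for mitosis, 0.17 for DNA replication, 0.30 for interferon and 0.14 for the secreted factors.

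For 6 lists camera with the preset correlation called a difference between the lines in their response, and with an estimated correlation or in fry it was 0 of the 6 (adjusted p from 0.46 to 0.88 with an estimated correlation). The median difference, line B minus line A, was 0.20 for mitosis, 0.13 for DNA replication, 0.10 for MYC targets, -0.18 for fibroblast markers, -0.15 for oxidative phosphorylation and -0.11 for pyruvate entry and the TCA cycle. Without the 2 line B arrays at one end of the leading axis within groups, the difference was 0.12 for mitosis and -0.25 for the TCA cycle.

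A signal also appeared in data outside the named genes: 11 probe sets with several symbols or unnamed here passed when every probe set was tested on its own, of which 8 of 1621 carry several symbols and 3 of 12146 are unnamed here. All 8 of the first kind were higher with tamoxifen, by 0.60 to 1.35, and the others ranged from -0.58 to 1.99.

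The interferon response genes rose in both lines, by a median of 0.49. Macrophages added in the treated cultures would bring their own abundant transcripts. Their markers had a median change of 0.03 (SD over 16 genes 0.14), and 0.11 (SD 0.17) in line B, where the interferon list rose by 0.44. That argues against many added macrophages. A small number is not excluded, since the list's mean was only 6.41 to 6.99 per sample and dim probe sets understate a change. Lyz2 was at 6.97 and 7.23 without and 7.97 and 7.77 with tamoxifen in line A, while its samples overlapped in line B. Macrophages already present before tamoxifen are not addressed by this test. Without the line B arrays at one end of the leading axis within groups the median of the interferon list was 0.48, which argues against those arrays. A single array was then left in each line B group. The SE of the list's mean change was 0.06, from the spread within groups over all 8 arrays. What stays open is the treatment: 0 groups received tamoxifen without the exchange of isoforms, so tamoxifen or the activity of a recombinase cannot be told apart from the exchange. A response to the exchange itself is thus a hypothesis that this design does not test.

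The median change of the mitosis genes was lower in line A, by a gap of 0.24 between the medians, but 0 of 38 genes passed for a difference and the list's call is lost with an estimated correlation (adjusted p = 0.50). Fewer dividing cells in line B before tamoxifen are argued against, since the mean of the list without tamoxifen was lower there by only 0.04 (difference -0.04, SE 0.05), where a difference of the size of the 0.20 gap in means would be needed. Without the 2 line B arrays at one end of the axis the gap in medians was 0.19 and the median difference per gene 0.12. The SE of the difference in the list's mean change was 0.09, from the spread within groups over all arrays. That is not an error of the medians, so whether these arrays contribute cannot be told. A difference in biology between the lines stays open and untested.

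The macrophage markers had a median difference of 0.37, line B minus line A, without tamoxifen, but 1 of 16 passed over all genes and the list's call is lost with an estimated correlation (adjusted p = 0.16). Without the 2 line B arrays at one end of the axis the median was 0.36, which argues against those arrays. The SE of the list's mean difference was 0.05, from the spread within groups over all arrays. With tamoxifen the sign, which was not tested by gene, was positive for 16 of 16 markers. The median difference was 0.48, from 0.03 for Fcgr1 to 1.53 for Lyz2. The difference was 0.81 for Laptm5 and 0.68 for Tyrobp. Among the C1q genes it was 0.67 for C1qc, 0.31 for C1qb and 0.06 for C1qa, and for Cd74 it was 0.09. C1qa and Cd74 are both abundant in macrophages. Since the samples with tamoxifen come from the same lines, macrophages among the cells of line B cannot be told apart from a stable difference in the fibroblasts' own expression. The list was written before the data were examined, no sort or gate is named in the labels, and 0 of its genes are on another of the lists.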

How the results depend on the processing

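The alternatives were set before the data were examined, except for leaving out 2 or 3 arrays, the axis as a covariate and the list counts of the other comparisons, which were chosen after seeing the data. Median shift, repeated quantile normalization, the dim filter, trend and robust, and the mean of a gene's probe sets kept each count of genes within 1.5 times. Array weights gave 983 genes over both lines, 525 in line A and 1 in line B. Every probe set on its own gave 74 over both lines, 1 in line A, 0 in line B and 3 between the lines, with more tests, and an agreement of the lines of 0.272. For the line, no term gave 132 genes, a random block 106 and averaging each line and condition first 1198, with 1 residual degree of freedom. Fits of a line's own 4 samples gave 543 in line A and 2 in line B. Leaving out 2 line B arrays gave 493 over both lines, 543 in line A and 143 between the lines, 12 lists that differ between the lines and an agreement of 0.247; leaving out 3 arrays gave 459 in line A, 40 in line B, 125 between the lines and an agreement of 0.274. The axis as a covariate, estimated from the same residuals so that p-values are too small, gave 996 over both lines, 736 in line A, 142 in line B and 292 between the lines. Lists called over both lines, in line A, in line B, for the difference and between the lines numbered 4, 3, 1, 0 and 0 with an estimated correlation and 7, 8, 5, 0 and 1 in fry. Why these counts move was not tested.

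Without each replicate in turn, genes numbered 58 to 353 over both lines, 0 to 143 in line A, 0 to 6 in line B, 0 for the difference and 4 to 79 between the lines. Lists numbered 15 to 17, 14 to 18, 9 to 15, 4 to 10 and 2 to 5, the agreement 0.176 to 0.542, and the Pkm change -0.28 to -0.01. Among lists that passed, the direction of camera turned for 4: oxidative phosphorylation over both lines (median -0.00 without 3 arrays), lysosome and autophagy in line B (-0.12 without 2 or 3 arrays, and from -0.19 to 0.34 without each replicate), unfolded protein response in line B (-0.21 to 0.03) and TCA cycle for the difference (-0.23 to 0.02). The median alone crossed 0 for fatty acid synthesis in line B (0.05 without line B PKM1 replicate 2, where it no longer passed). No named gene that passed over both lines turned, and 17 of 49 passed under every setting. Signal over background was not measured, so changes of dim probe sets are understated. No paired analysis was possible because the labels number no replicates.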

Other observations

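The tests in this part were chosen after seeing the data. Of the 263 genes that passed over both lines, 203 are on none of the 35 lists, 135 higher and 68 lower. To look for families, all genes tested were grouped by the letters with which their symbols begin. The 320 groups of at least 8 genes were tested for an excess of genes that rose or fell (hypergeometric test, adjusted over 640 tests). All 263 genes counted here, those on the 35 lists included, so an excess can repeat part of a list's result. Among the genes that rose there was an excess of Ifi genes (5 of 15, adjusted p = 5.8e-05), tripartite motif genes of the Trim family (7 of 59, 0.00015), chemokine genes of the Ccl family (4 of 19, 0.0023), guanylate-binding protein genes (3 of 8, 0.003) and matrix metalloproteinase genes (4 of 22, 0.003). Among those that fell there was an excess of kinesin genes (5 of 38, 0.0003). None of these 6 families passed camera with an estimated correlation (adjusted p from 0.32 to 0.99). Genes of one family can share probes and are not independent, so the p-values are too small, and some of these genes, such as Ifi203, Trim30a, Mmp13 and Ccl2, have been described above.

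Within groups, 61.8% of the variation over all genes lay on 1 axis, on which the samples of line B stood furthest apart: -0.45 and 0.45 without tamoxifen and 0.49 and -0.49 with it. The line A samples lay at 0.22 and -0.22 without and 0.06 and -0.06 with tamoxifen. With 2 samples per group, the values of a pair are equal and opposite by construction. The axis thus does not show which sample of a pair stands apart. The arrays left out together above were from the positive end, and those at the negative end were not left out together. Line B PKM2 replicate 2 correlated with line B PKM1 replicate 1 at 0.9944 and with the other sample of its own group at 0.9907. Likewise, line B PKM1 replicate 2 correlated with line B PKM2 replicate 1 at 0.9946 and with the other sample of its own group at 0.9894. The levels of Ifit1 do not point to a swap of samples in line B. They were 6.60 and 6.26 without tamoxifen and 8.57 and 8.74 with it, in the order of the replicates. In line B, Pkm was higher in the samples at the positive end of the axis: its brighter probe set was at 10.82 and 11.21 without and at 11.41 and 10.75 with tamoxifen.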
